A study of Homo sapiens with 18 samples.

How the data were processed

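Primary human CD4+ T cells from 2 donors were isolated from frozen blood mononuclear cells, per the labels. They were rested or activated for 3, 6, 9 or 24 h with water or with metformin and 2-deoxyglucose. The labels' protocol describes activation for 24 h while the titles and series text give 0 to 24 h, and the titles were followed. Doses are not given in the sources used here, nor is the time of drug addition given in the labels. RNA was sequenced with a custom targeted panel in which each target is 1 short stretch of a transcript and a UMI tags each captured molecule. The protocol text also names a stranded whole-transcriptome kit, and the files match the targeted panel only.

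The counts used are the deposited whole-number UMI counts per panel target and library, not normalized, per the file headers. The submitters had counted them after dropping short, unmapped, off-target and poorly aligned reads, per the file headers. Deposited read counts per target, from the same files, served as an alternative. Other deposited values, the read totals per library, were used for depth. The submitters' processing notes name STAR, DESeq2, GRCh38 and hg38, with no version or role, and the aligner's settings are not given in the sources used here. Of 547 targets 531 were panel genes, 10 were genes that the files mark as reference genes and 6 were genomic DNA controls. The genomic DNA controls held 0 UMIs in all 18 libraries. Of 541 gene identifiers 540 matched a table of gene names. By the coordinates in the files, 532 of 541 targets lay in exons of GENCODE release 29 (GRCh38) and 9 were not placed. Their spliced length was 90 to 130 bp with a median of 95, with 465 in 1 exon, 332 in coding sequence and 133 in 3′ UTRs. BLAST+ 2.17.0 found 38 targets with a copy in another gene's transcripts (at least 95% identity over at least 80% of the target), and named genes among them are called uncertain.

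Libraries held 720707 to 1399125 UMIs, and 493 to 509 genes reached 10 UMIs. The median standard error was 0.24 on the log2 scale for activation at 3 h. Ratios and floors for genes near 0 cover counting error only. Where a group had no UMI, the fold is against 3 counts over its 2 libraries, and with 1 to 3 UMIs the ratio has an exact binomial 95% interval. Chi-square per degree of freedom between the replicates of 1 group was 39.0 to 70.5, where counting noise alone gives 1, so no library was a copy of its replicate.

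Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F test, Benjamini-Hochberg within each comparison, threshold 0.05). The filter kept 521 of 541 genes. All 18 libraries entered 1 fit of 9 group means with 9 residual degrees of freedom, so all groups shared the estimate of spread. There were 12 contrasts and 2 F tests over times. The common biological coefficient of variation was 0.257. Groups, contrasts, lists and the rule for naming genes were set before the data were examined. Same-numbered libraries of different groups come from the same donor, per the labels, so the numbers pair the samples. Their deviations from the group means correlated in all 36 pairs of groups (r 0.542 to 0.849, median 0.681). The 9 residual degrees of freedom therefore share a difference between the donors and are not independent. The fit with the donor as a block (8 residual degrees of freedom, coefficient of variation 0.128) was set as an alternative, and its values are given beside the counts for the drug and the calls that it changed. In simulated data with 200 of 521 genes changed, drawn 5 times, activation at 24 h recovered 35.7, 69.2 and 94.6% of changes of 1.5, 2 and 4-fold. The drug at 24 h recovered 30.8, 69.3 and 92.4%, and the drug average 76.7, 93.7 and 99.1%. With the block these were 73.5, 91.5 and 97.5%, 63.2, 88.4 and 99.1%, and 89.0, 96.7 and 99.1%. False calls made up 0, 0 and 0.885% of calls, and 2.53, 3.58 and 3.17% with the block. The simulated counts were drawn from the blocked fit, with the same donor difference in every group. They therefore favour the block, and its share of false calls does not cover responses that differ between donors.

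The 29 gene lists were tested with limma 3.58.1 on log2 CPM (prior count 2): camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Lists needed 3 tested members for these tests. Lists of mitochondrial-genome electron transport genes, glucose-regulated endoplasmic reticulum proteins, B cells, CD8 T and natural killer cells, and platelets and red cells had no panel members. Named genes passed the test, moved the same way in both donors and had at least 50 UMIs per library in the higher group. They were the 10 largest changes each way for activation and drug at 24 h, the 5 largest each way for activation at 3 h, drug at 3 h, drug average and control 24 h against 3 h, and up to 3 per list and comparison. The fixed background genes HK2, LDHA, ASNS, PRKAA1 and PDK1 were named whatever their result. Of the genes named outside the rule, PGK1 in treated cells and UGDH, SLC17A5 and NFYB at 9 h were also chosen after their values were seen, as marked elsewhere for the rest. Of the genes that the rule names, 1 also lies on the Y chromosome and was left unnamed, and 1 panel gene with common deletions was not reported.

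Alternatives were DESeq2 size factors, total UMIs, 3 common reference genes, the DESeq2 1.42.0 test, limma-voom, no filter, a filter at a mean of 50 UMIs, the donor block, read counts, only the groups compared, other prior counts, and leaving out each library. Scaling by the panel's 10 reference genes and leaving a time out of the drug average were added later. Leaving out 1 library leaves its group with 1, which is then assumed to vary like the other groups. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for annotation and plots.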

Results

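Transcripts of 541 mostly metabolic genes were counted by targeted RNA sequencing in primary human CD4+ T cells from 2 donors. Cells were rested (0 h) or activated for 3, 6, 9 or 24 h with soluble complexes that bind CD3 and CD28, the T cell receptor complex and a costimulatory receptor. Activated cells received water (control) or metformin with 2-deoxyglucose (drug). Metformin is a biguanide that inhibits mitochondrial respiration, and 2-deoxyglucose is a glucose analogue that blocks the early steps of glycolysis. The 18 libraries fell into 9 groups with n = 2, 1 library per donor. Unique molecular identifiers (UMIs), tags that count each captured molecule once, came to 720707 to 1399125 per library. Rested libraries held 769163 ± 68527 UMIs (mean ± SD) and control libraries at 24 h held 1348312 ± 71860, with 1202230 ± 70596 in drug libraries at 24 h. Sequencing gave 2.65 ± 0.56 reads per UMI in rested cells and 1.48 ± 0.05 in control cells at 24 h. The 10 most abundant genes took 43.5 to 52.8% of a library's UMIs. B2M, which encodes the light chain of MHC class I, alone took 29.7% ± 0.79 in rested cells, 17.2% ± 3.09 in control cells at 24 h and 20.6% ± 2.35 in drug cells at 24 h. Levels are given as TMM-scaled CPM (UMI counts as parts of a library total of 1e6). They compare groups for 1 gene but not genes with each other, since primers differ in efficiency.

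Changes are log2 fold changes ± standard error from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p, and every group in a comparison had n = 2. Each gene described as risen or fallen moved the same way in both donors. The first question was how resting CD4+ T cells change their metabolic transcripts on activation. Rested cells were sampled at 0 h only, so effects of activation cannot be told apart from those of time in culture. Changes with activation here mean the difference from these rested cells. Genes are ranked among those with at least 50 UMIs per library in the higher group. After 24 h in water the largest measured rises were in IL10, GAD1, IL4 and TYMS. PLA2G4A, a phospholipase that releases arachidonic acid, had 108 UMIs against 0 in rested cells, at least 21.7-fold higher over a floor of 3 counts for the group (adjusted p = 0.00568), so it has no place in this order. IL10, an immunoregulatory cytokine, rose by 7.91 ± 1.30 (2095 against 8.65 CPM, adjusted p = 0.000237), and IL4, a T helper cytokine, rose by 5.03 ± 0.60 (926 against 28.3 CPM, adjusted p = 2.83e-05). TYMS, which makes thymidylate for DNA, rose by 4.80 ± 0.75 (12871 against 461 CPM, adjusted p = 0.000163), though its count is uncertain because the target matches an overlapping gene. MAOA, which oxidises amines, rose by 4.62 ± 0.76 and PFKFB4, which sets the level of a glycolysis activator, rose by 4.15 ± 0.55. The folate hydrolase GGH rose by 3.80 ± 0.73 and the lipoprotein receptor VLDLR by 3.44 ± 0.51. GAD1, which makes the transmitter GABA, rose by 5.18 ± 1.51 (adjusted p = 0.00941), but lost its call without control 24 h replicate 2 (adjusted p = 0.0992) or rested replicate 1 (0.0717). DHRS2, a short-chain dehydrogenase, rose by 4.13 ± 1.27 and lost its call without control 24 h replicate 2 (adjusted p = 0.17), rested replicate 1 (0.0624) or rested replicate 2 (0.0754).

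Falls at 24 h were also large. PTGDS, a prostaglandin synthase, had 1 UMI against 361, a ratio of 578 (95% counting interval 103 to 22881.8), and the peptidase ACE had 3 against 234, a ratio of 125 (42.2 to 610). Both are uncertain because their targets match overlapping genes. The urea channel SLC14A1 fell by 5.88 ± 0.73, the adenosine deaminase CECR1 fell by 5.09 ± 0.65 and the kinase NUAK2 fell by 4.57 ± 0.66. AQP3, a water and glycerol channel, fell by 4.29 ± 0.41 (181 against 3549 CPM, adjusted p = 5.89e-06). TCF7, a transcription factor of naive and memory T cells, fell by 4.06 ± 0.72 (240 against 3997 CPM, adjusted p = 0.000397). TSC22D3, a glucocorticoid-induced regulator, fell by 4.07 ± 0.67, the sorting receptor SORL1 fell by 4.07 ± 0.33 and ADHFE1, an alcohol dehydrogenase, fell by 3.75 ± 0.47. FOXO1, a transcription factor of quiescent T cells, fell by 1.86 ± 0.22.

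Across the panel 341 of 521 tested genes changed at 24 h, 188 upward and 153 downward, of which 121 and 93 changed at least 2-fold. The same test called 285 genes at 3 h (147 up, 138 down), 342 at 6 h (176 up, 166 down) and 354 at 9 h (184 up, 170 down), and 439 differed at any time. The split of directions depended on the scaling, and scaling by the panel's own 10 reference genes, added after the data were examined, gave the largest shift. It moved the median change of all genes at 24 h from 0.10 to 0.80 and the calls to 286 up and 68 down. At 24 h 7 of those 10 genes were themselves called lower, from -0.46 for MAP3K2 to -2.45 for ZBTB22 (genes chosen after their values were seen). At 3, 6 and 9 h this scaling gave 209 up and 57 down (median 0.43), 235 and 102 (0.51), and 250 and 89 (0.60). Scaling by total UMIs gave 104 up and 212 down at 3 h (median -0.43) and 143 and 204 at 6 h (-0.28), with medians of -0.19 at 9 h and -0.03 at 24 h. Scaling by 3 common reference genes gave 89 up and 226 down at 3 h (median -0.54) and 134 up of 341 called at 6 h (-0.32), with medians of -0.19 at 9 h and -0.06 at 24 h.

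Most genes of the glycolysis list, which turn glucose into pyruvate and lactate, rose at 24 h. Of 20 tested members 14 were higher and 2 lower, the same counts adjusted over the list alone, with a median change of 1.70. ENO1 rose by 2.93 ± 0.25 (adjusted p = 3.69e-06), and TPI1 rose by 2.90 ± 0.26 (adjusted p = 4.28e-06), the latter uncertain because its target has 4 near-identical copies. LDHA, which makes lactate, rose by 2.38 ± 0.28 and HK2, the inducible hexokinase, rose by 2.10 ± 0.42. PGK1 rose by 0.98 ± 0.31 (412 against 209 CPM) and lost its call without control 24 h replicate 2 (adjusted p = 0.0675) or rested replicate 1 (0.0908). The lactate carriers SLC16A1 and SLC16A3, both tested members of the transport list, rose by 1.75 ± 0.28 and 1.49 ± 0.17, the latter uncertain because its target matches an overlapping gene. The camera list test called glycolysis with a preset correlation (adjusted p = 0.0102), and gave adjusted p = 0.502 with an estimated correlation. In the pentose phosphate pathway 4 of 6 members rose and 1 fell (5 and 1 adjusted over the list alone), led by RBKS, which phosphorylates ribose (2.06 ± 0.22), and PGD (1.69 ± 0.28), uncertain because of a near-identical copy. Among 8 glycogen and gluconeogenesis genes 3 rose and 2 fell, and among 22 pyruvate dehydrogenase and TCA cycle genes 7 rose and 5 fell. IDH3A, a TCA cycle dehydrogenase, rose by 1.67 ± 0.30, and CYCS, the respiratory electron carrier cytochrome c, rose by 1.96 ± 0.32, 1 of 4 risen among 9 nuclear electron transport genes. The counts in the last 4 lists were 5 up and 0 down, 5 and 1, 15 and 0, and 8 and 0 under the panel's reference-gene scaling.

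Lipid genes were counted by list at 24 h. Of 10 fatty acid synthesis genes 6 rose and none fell, including FADS1, a desaturase (3.01 ± 0.46), SREBF1, the sterol and fatty acid regulator (2.97 ± 0.15, adjusted p = 9.27e-08), and FASN, the fatty acid synthase (1.96 ± 0.29). Of 23 cholesterol synthesis and uptake genes 16 rose and 3 fell (17 and 3 adjusted over the list alone). Camera called the cholesterol list (adjusted p = 0.0336, and adjusted p = 0.502 with an estimated correlation) and not fatty acid synthesis (adjusted p = 0.0557), which the fit with a donor block called (0.0389, and 0.226 with an estimated correlation). Of 28 fatty acid oxidation genes 6 rose and 12 fell with a median of -0.22, but the panel's reference-gene scaling turned this to 14 up and 2 down with a median of 0.48. The largest fall in that list was in ACSL6, an acyl-CoA synthetase, at -3.01 ± 0.35 and -3.45 ± 0.33 for its 2 targets, the latter uncertain because it matches an overlapping gene.

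Several lists for nucleotides and amino acids had more members up than down at 24 h. All 4 pyrimidine and deoxynucleotide genes rose, as did 4 of 6 purine synthesis genes with none falling. CAD, which starts pyrimidine synthesis, rose by 1.57 ± 0.24, and HPRT1, which salvages purines, rose by 1.75 ± 0.31. Of 16 serine, glycine and one-carbon genes 10 rose and 3 fell, led by PHGDH, the entry to serine synthesis (3.39 ± 0.45). PYCR1, which makes proline, rose by 3.28 ± 0.47, and 5 of 9 genes of glutamine, aspartate and branched-chain amino acids rose with none falling. Of 8 polyamine and arginine genes 5 rose and 2 fell. ARG2, an arginase, rose by 3.31 ± 0.52 and SMS, spermine synthase, by 1.90 ± 0.15 (uncertain because of a near-identical copy), while SAT1, which breaks polyamines down, fell by 1.82 ± 0.17. In hexosamine and N-glycan precursor synthesis 4 of 7 genes rose (3 adjusted over the list alone), and in the glutathione, thioredoxin and antioxidant list 4 of 13 rose and 3 fell, where catalase (CAT) fell by 1.62 ± 0.24. Of 9 integrated stress response genes, the ATF4 programme that answers amino acid or mitochondrial stress, 7 rose and none fell, with a median of 2.56. The list shares CTH, MTHFD2, PHGDH and PSAT1 with the serine list and ASNS with the glutamine list. CHAC1, a glutathione-degrading enzyme of that programme, rose by 3.24 ± 0.63. Camera called the list (adjusted p = 0.041, and adjusted p = 0.502 with an estimated correlation), and the donor block ended that call (adjusted p = 0.0561). SLC7A11, the cystine carrier and sole amino acid transport gene tested, rose by 2.56 ± 0.73 (24.1 against 3.94 CPM, adjusted p = 0.00842; chosen after its values were seen).

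Signalling and identity genes followed different directions. Of 11 AMPK and mTOR genes none rose and 6 fell with a median of -0.76, and the autophagy kinase ULK1 fell by 1.70 ± 0.29. The panel's reference-gene scaling left 2 up and 3 down there (median -0.06), and the donor block took the camera call across the threshold (adjusted p = 0.0461 against 0.0513, and 0.441 with an estimated correlation). Of 6 NAD and sirtuin genes none rose and 3 fell (median -0.60), which the panel's reference-gene scaling turned to 2 up and none down (0.09). Of 11 transcriptional regulators 4 rose and 4 fell, and PPARG, a nuclear receptor for lipids, rose by 2.42 ± 0.59. Among 6 T cell activation genes 4 rose and none fell, among them IL2, a T cell growth factor (3.25 ± 1.11, adjusted p = 0.0215), which lost its call without control 24 h replicate 2 (0.13), rested replicate 1 (0.106) or rested replicate 2 (0.0883). Of 9 common reference genes, among which LDHA, PGK1 and GAPDH are also in the glycolysis list and HPRT1 and SDHA in others, 4 rose and 1 fell. Of 4 tested myeloid genes none rose and 2 fell. ASNS, which makes asparagine, was not called (0.04 ± 0.33, adjusted p = 0.924). PDK1, a brake on pyruvate dehydrogenase, was called only with the donor block (0.26 ± 0.30, adjusted p = 0.462, blocked 0.0433). Without the donor block these p-values rest on a spread that includes the baseline difference between the 2 donors. They do not measure how far the 2 donors' responses differ. In simulated data with changes of 2-fold this comparison recovered 69.2% of them.

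**Figure D1:**
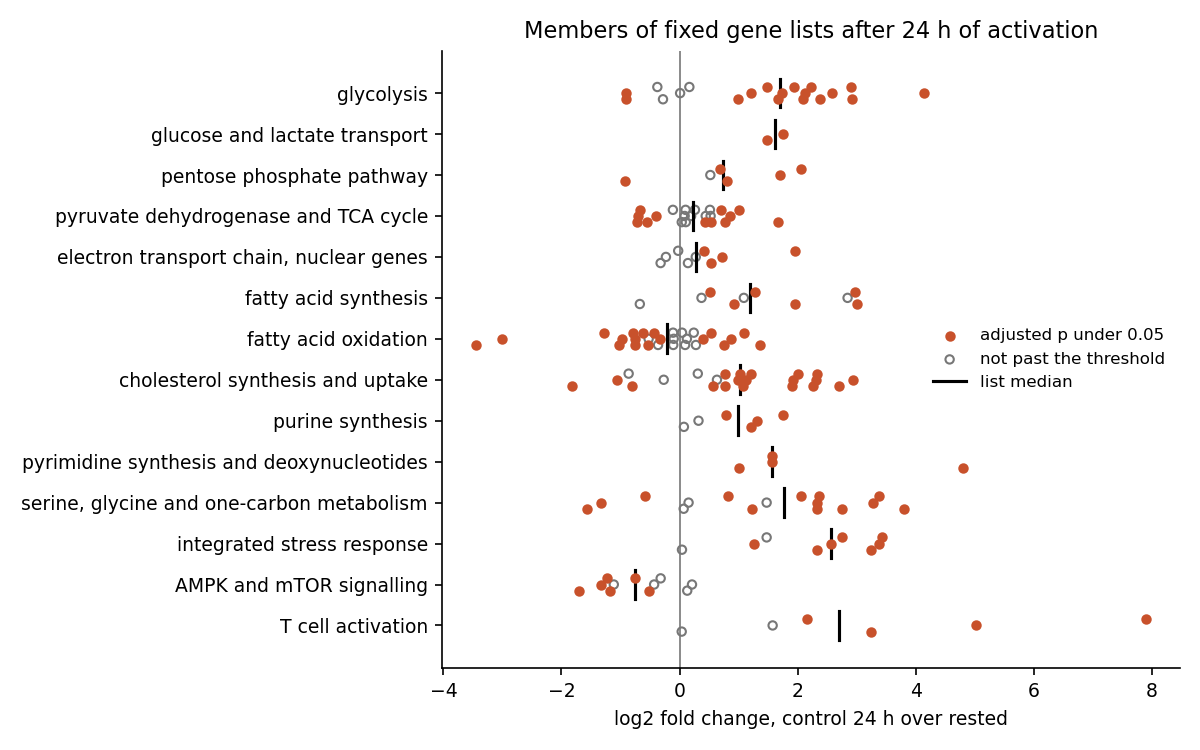
Log2 fold change of each tested member (points, filled where adjusted p was under 0.05) of 14 gene lists in control cells at 24 h over rested cells, n = 2 donors per group, with each list's median as a bar. The glycolysis median was 1.70 and the AMPK and mTOR median -0.76; the fatty acid oxidation median of -0.22 became 0.48 when libraries were scaled by the panel's own reference genes.

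The next question was when these changes appear. At 3 h cytokines and stress response genes were among the largest rises, with IL4 up by 6.30 ± 0.62 (adjusted p = 7.73e-06), IL2 up by 5.94 ± 1.22 (2724 against 44.3 CPM, adjusted p = 0.00152) and IFNG, the main T helper 1 cytokine, up by 5.20 ± 0.79 (6771 against 183 CPM, adjusted p = 0.000183). CHAC1 rose by 6.12 ± 0.66 (652 against 9.36 CPM, adjusted p = 1.4e-05) and SLC7A11 by 5.77 ± 0.73. The largest named falls were in TSC22D3 (-4.16 ± 0.68), NUAK2 (-3.79 ± 0.64), ACSL6 (-2.70 ± 0.35) and IDH1, a cytosolic isocitrate dehydrogenase (-2.55 ± 0.35). MTHFD2, a mitochondrial folate enzyme, rose by 3.73 ± 0.28 (adjusted p = 1.61e-06), PSAT1, the second step of serine synthesis, rose by 3.53 ± 0.44 and ODC1, which starts polyamine synthesis, rose by 2.17 ± 0.13. HIF1A, the oxygen-sensing regulator, rose by 2.44 ± 0.19 and PPARG by 5.07 ± 0.63. Of 6 T cell activation genes the 5 cytokines rose at 3 h, and CD28 (chosen after its values were seen) fell by 0.30 ± 0.12, which the panel's reference-gene scaling turned to 0.22. The integrated stress response list had 7 of 9 up and none down (camera adjusted p = 0.0184, and 0.698 with an estimated correlation), and the T cell activation list was also called (0.0429, and 0.553 with an estimated correlation); the panel's reference-gene scaling ended both calls (0.0549 each). Fatty acid oxidation had 3 of 28 up and 13 down with a median of -0.74 (camera adjusted p = 0.0184, and 0.553 with an estimated correlation), a call that the panel's reference-gene scaling ended (6 up and 9 down, adjusted p = 0.0544).

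Glycolysis at 3 h had 7 members up and 2 down, with a median of 0.26, but scaling by common reference genes gave 5 up and 6 down with a median of -0.19, and total UMIs a median of -0.09. PKM, the pyruvate kinase, rose by 1.92 ± 0.16 and PFKP, a phosphofructokinase, by 1.72 ± 0.16. Fatty acid synthesis had 3 up and 3 down at 3 h (3 and 4 adjusted over the list alone), cholesterol 9 up and 8 down, and serine and one-carbon genes 9 up and 1 down. HK2 rose by 3.23 ± 0.43 at 6 h, ODC1 by 2.68 ± 0.13 (adjusted p = 7.56e-08) and IL4 by 7.94 ± 0.65, to 6947 CPM. At 9 h cholesterol genes had 18 of 23 up and 4 down, and all 6 T cell activation genes were up. IL10 peaked at 9 h among the times measured (3487 CPM), while IL2, IFNG and TNF peaked at 3 h. In control cells, 302 genes differed between 24 h and 3 h (148 higher, 154 lower), and the scalings by total UMIs, common reference genes and the panel's reference genes gave 187 and 113, 196 and 99, and 166 and 108. PFKFB4 was higher at 24 h than at 3 h by 5.95 ± 0.63, TYMS by 4.98 ± 0.75 and FADS1 by 4.40 ± 0.50. AHR, the aryl hydrocarbon receptor, was lower at -3.77 ± 0.26 (adjusted p = 6.82e-07, uncertain because of an overlapping match), QPCT, a glutaminyl cyclase, at -5.99 ± 0.73, CECR1 at -4.24 ± 0.63 and IFNG at -3.63 ± 0.73. Between these times 11 glycolysis genes were higher and 1 lower, 6 fatty acid synthesis genes higher and none lower (7 adjusted over the list alone), and 14 cholesterol genes higher and 1 lower. Camera gave adjusted p = 0.012 for each of the 3 lists, and 0.582, 0.184 and 0.582 with an estimated correlation. The stress response list had 2 higher and 5 lower, with CHAC1 at -2.89 ± 0.53 and SLC7A11 at -3.21 ± 0.58.

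**Figure D2:**
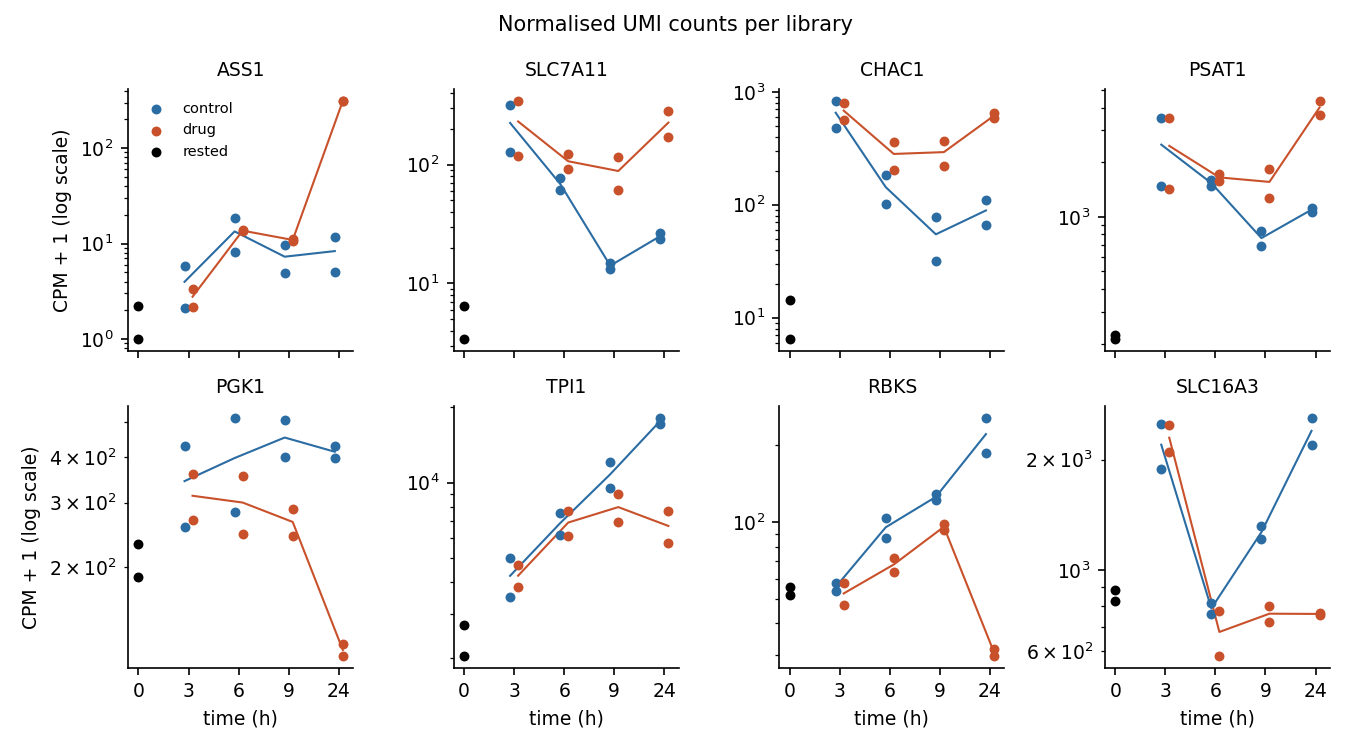
TMM-scaled CPM (log axis) of selected genes in rested cells and in control and drug cells at 3, 6, 9 and 24 h, with each donor's library as a point and the mean of n = 2 as a line. CHAC1 stood at 652 CPM in control cells at 3 h and 88.0 at 24 h, against 613 in drug cells at 24 h.

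The central question was how metformin with 2-deoxyglucose changes the activated cells. At 24 h the largest rise over water was in ASS1 (ENSG00000130707), which makes argininosuccinate from citrulline and aspartate. It rose by 5.39 ± 0.60 (310 ± 1.31 against 7.33 ± 4.60 CPM, mean ± SD, adjusted p = 0.000211), measured at chromosome 9, 130501091 to 130501202, in the 3′ UTR of exon 15. SLC7A11 (ENSG00000151012, chromosome 4, 138185150 to 138185240, exon 7) rose by 3.22 ± 0.58 (225 against 24.1 CPM, adjusted p = 0.00455). CHAC1 (ENSG00000128965, chromosome 15, 40955543 to 40955647, exon 3) rose by 2.80 ± 0.52 (613 against 88.0 CPM, adjusted p = 0.00489). PSAT1 rose by 1.87 ± 0.41 (4001 against 1093 CPM, adjusted p = 0.00924), and ASNS, uncertain because its target matches an overlapping gene, rose by 1.73 ± 0.34 (1158 against 350 CPM, adjusted p = 0.00555). The prostaglandin synthase HPGDS rose by 2.95 ± 0.54, FYN, a kinase of the T cell receptor, by 1.44 ± 0.22, and SLC17A5, a lysosomal sialic acid carrier, by 1.40 ± 0.17 (adjusted p = 0.000285). PHGDH rose by 1.49 ± 0.41 (adjusted p = 0.0323) and GPT2, a mitochondrial alanine transaminase, by 1.85 ± 0.54 (adjusted p = 0.049). CD38, an ectoenzyme that consumes NAD, rose by 1.18 ± 0.20 (2497 against 1100 CPM, adjusted p = 0.0043).

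The largest falls with drug at 24 h, among genes with at least 50 UMIs per library in the higher group, were in CKB, RBKS and PFKFB4. RBKS (ENSG00000171174, chromosome 2, 27843139 to 27843230, exon 5) fell by 2.88 ± 0.22 (29.8 against 220 CPM, adjusted p = 1.26e-05). CKB, the brain creatine kinase (ENSG00000166165, chromosome 14, 103519745 to 103519837, 3′ UTR of exon 8), fell by 2.96 ± 0.40 (19.1 against 150 CPM, adjusted p = 0.000879). PFKFB4 fell by 2.85 ± 0.50 (35.9 against 260 CPM), PGK1 fell by 1.81 ± 0.32 (117 against 412 CPM), PGAM1 fell by 1.62 ± 0.28 and TPI1 fell by 1.39 ± 0.25 (6712 against 17638 CPM), each with adjusted p = 0.0043. SLC16A3 fell by 1.66 ± 0.17 (758 against 2395 CPM, adjusted p = 0.000169). The glutathione transferase MGST2 fell by 1.74 ± 0.37, glutamine synthetase (GLUL) fell by 1.58 ± 0.31 (336 against 1006 CPM) and ISYNA1, which makes inositol phosphate, fell by 1.46 ± 0.29. Of 57 genes called at 24 h 28 rose and 29 fell, 15 and 18 of them at least 2-fold, and with the donor block 172 were called (88 up, 84 down). Scaling by total UMIs gave 48 up and 26 down (median 0.12) and by the panel's reference genes 13 up and 73 down (median -0.36). Of those 10 genes MAP3K2 and ZBTB22 were themselves higher with drug, by 0.76 and 1.12 (chosen after their values were seen).

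Single libraries mattered for some of these calls. Without control 24 h replicate 2 the count at 24 h dropped to 35, and without drug 24 h replicate 1 to 33. ASNS and CHAC1 missed the threshold without control 24 h replicate 1 (adjusted p = 0.0506 for both), and PSAT1 without control 24 h replicate 1 (0.0743) or 2 (0.0788). GLUL (0.0595), ISYNA1 (0.0565) and LDHA (0.0691) missed it without drug 24 h replicate 1, and MGST2 without drug 24 h replicate 2 (0.0713). PHGDH lost its call in 6 of 18 such omissions and GPT2 in 12, with the highest values without control 24 h replicate 2 (0.181 and 0.194), and neither was called under the panel's reference-gene scaling (0.115 and 0.102). ASS1, SLC7A11, RBKS, CKB, PFKFB4, PGK1, PGAM1, TPI1 and SLC16A3 kept their calls whichever library was left out.

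Glycolysis was the list with the most called members with drug at 24 h. Of 20 members none rose and 15 fell, also adjusted over the list alone, with a median of -0.94, and at least 15 fell under each of the 4 other scalings. The fallen genes ran from PFKFB4 (-2.85) to PKM (-0.64, adjusted p = 0.0173), and included LDHA (-1.27 ± 0.26, adjusted p = 0.00636), GAPDH (-1.03 ± 0.20, adjusted p = 0.00555) and ENO1 (-0.95 ± 0.23, adjusted p = 0.019; ENO1 and PKM chosen after their values were seen). HK2 was called only with the donor block (-0.65 ± 0.40, adjusted p = 0.304, blocked 0.00965), and PFKFB2, an activator of phosphofructokinase, was not called (0.70 ± 0.41). Camera gave adjusted p = 1.23e-09 with a preset correlation and adjusted p = 0.207 with an estimated correlation, or 0.0109 with an estimated correlation in the blocked fit. The fry test of whether members move one way gave adjusted p = 0.000408. The integrated stress response list had 5 of 9 members up and none down (8 up adjusted over the list alone), with a median of 1.73. Camera gave adjusted p = 4.94e-05 and adjusted p = 0.322 with an estimated correlation, and fry gave 0.00726. The list's other members were CTH (2.07 ± 0.82, adjusted p = 0.118), MTHFD2 (0.58), PCK2 (0.89, called only with the donor block, 0.0171) and VLDLR (0.73), none called without the block and all chosen after their values were seen.

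**Figure D3:**
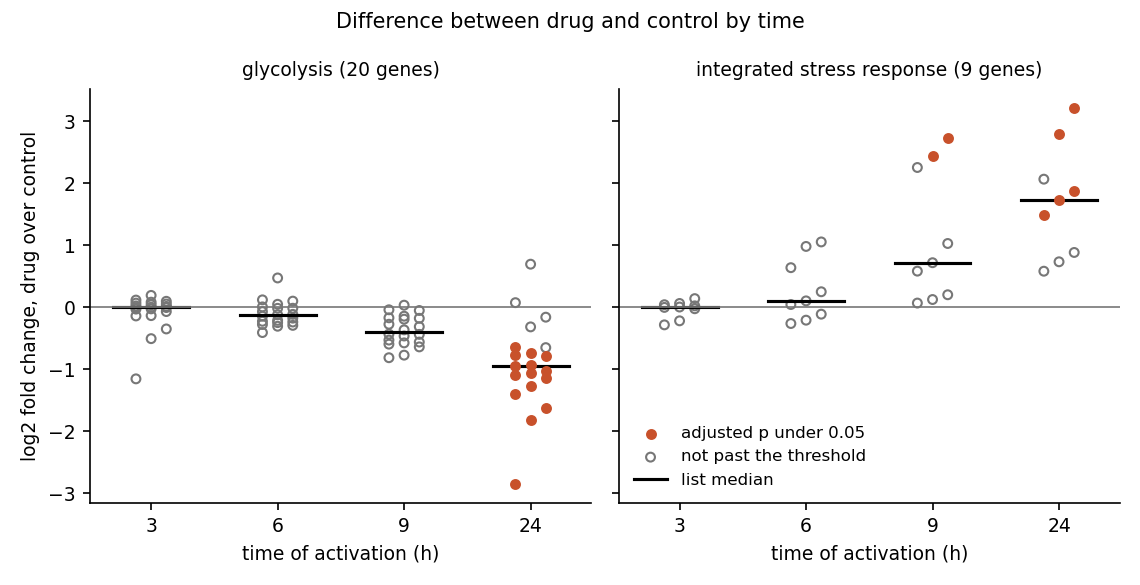
Log2 fold change of drug over water at 3, 6, 9 and 24 h for each tested member (points, with the list median as a line) of the glycolysis and integrated stress response lists, n = 2 donors per group. The glycolysis median was -0.000481 at 3 h and -0.94 at 24 h, and the stress response median 0.01 and 1.73; neither 24 h direction changed under another scaling.

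Other lists had fewer called members with drug at 24 h. Cholesterol genes had 1 up and 3 down with a median of -0.29 (camera adjusted p = 0.0299, and adjusted p = 0.731 with an estimated correlation), with HMGCS1, an early synthesis enzyme, at -1.21 ± 0.24 and IDI1, an isoprenoid isomerase, at -0.88 ± 0.18. HMGCS1 lost its call without control 24 h replicate 2 (adjusted p = 0.0524) or drug 24 h replicate 1 (0.0614), and IDI1 without the latter (0.0793). Fatty acid synthesis had no called member by edgeR (5 down with the donor block) and a median of -0.45, and camera called it only with the block (adjusted p = 0.0226 against 0.0846, and 0.202 with an estimated correlation). Serine and one-carbon genes had 3 up and none down, glutamine, aspartate and branched-chain genes 3 up and 1 down (4 and 1 adjusted over the list alone), and the polyamine and arginine list 1 up, ADI1, a methionine salvage enzyme (0.63 ± 0.12, adjusted p = 0.00462). The panel's reference-gene scaling gave 0 up and 1 down in that last list and ended the call of ADI1 (adjusted p = 0.142). Common reference genes had 3 down, all of them glycolysis members (LDHA, PGK1 and GAPDH; camera adjusted p = 0.0338, and 0.207 with an estimated correlation). The transport list had 1 down, the pentose phosphate pathway 1 down, the amino acid transport list 1 up, and NAD metabolism 1 up (CD38). Of the risen genes, PHGDH and PSAT1 (serine), ASNS (glutamine) and SLC7A11 (amino acid transport) are also in the stress response list. The counts of these lists are therefore not independent of it. AMPK and mTOR genes had 1 up (2 up and 2 down adjusted over the list alone), TSC2 at 0.59 ± 0.15, which lost its call without control 24 h replicate 1 (adjusted p = 0.0506), control 24 h replicate 2 (0.221) or drug 24 h replicate 1 (0.273), and the panel's reference-gene scaling gave 3 down and none up in that list. No member was called in glycogen and gluconeogenesis, the TCA cycle, nuclear electron transport, fatty acid oxidation, purines, pyrimidines, hexosamines (1 up and 1 down adjusted over the list alone), antioxidants, regulators, T cell activation or the myeloid list. In the blocked fit regulators had 5 up and 2 down and fatty acid oxidation 3 up and 2 down.

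T cell activation genes did not pass the test for the drug at 24 h without the donor block. IL10 stood at 1007 CPM with drug and 2095 in water (-1.06 ± 0.88, adjusted p = 0.49), IL2 at -1.25 ± 0.99 (0.458, but 0.00182 with the donor block), IFNG at 0.50 ± 0.66 (0.711) and IL4 at 0.79 ± 0.47 (0.287), all 4 chosen after their values were seen. PDK1 was called only with the donor block (-0.89 ± 0.30, adjusted p = 0.0704, blocked 3.52e-05). PRKAA1, a catalytic subunit of AMPK, moved by -0.06 and was not called. Simulated changes of 2-fold were recovered in 69.3% of cases at this comparison and changes of 1.5-fold in 30.8% (88.4 and 63.2% with the donor block), so smaller effects were often not detectable without the block.

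Earlier times of activation were compared next, and hours of activation need not be hours of drug exposure. At 3 h edgeR called no gene, and DESeq2, limma-voom and the blocked fit also called 0. In the main fit 0 of 521 genes had an unadjusted p under 0.05, where tests without any effect should give some. That fit ignores the pairing, although control and drug libraries of 1 donor deviated alike (r 0.796 to 0.849). It is therefore conservative for the drug, and this 0 is no added evidence of no effect. At 6 h edgeR called none (26 at an unadjusted p under 0.05, 5 by DESeq2, 0 by limma-voom). The blocked fit called 2 at 6 h, UGDH, which makes the UDP-glucuronate precursor (0.68, blocked adjusted p = 0.0122), and NFYB, a subunit of a promoter-binding factor (-0.64, blocked adjusted p = 0.0122), both chosen after their values were seen. At 9 h 8 genes were called, 7 up and 1 down, and 27 with the donor block (18 up, 9 down). UGDH rose by 0.89 ± 0.14 (adjusted p = 0.0141), GFPT1, the entry to hexosamine synthesis, by 0.92 ± 0.17, HSD17B4, a peroxisomal oxidation enzyme, by 1.11 ± 0.22, SLC17A5 by 0.81 ± 0.16 and ADI1 by 0.52 ± 0.12. SLC7A11 rose by 2.73 ± 0.60 (87.5 against 13.1 CPM) and CHAC1 by 2.44 ± 0.53 (292 against 53.7 CPM), both with adjusted p = 0.0487, and NFYB fell by 0.65 ± 0.14. Scaling by total UMIs gave 9 up and none down at 9 h. The count dropped to 4 or fewer in 13 of 18 omissions of a library, and to 0 without control 9 h replicate 1, control 9 h replicate 2 or drug 9 h replicate 1. Glycolysis had no called member at 9 h (2 down with the block) and a median of -0.40, with camera adjusted p = 1.65e-05, adjusted p = 0.277 with an estimated correlation, and 0.0374 with an estimated correlation in the blocked fit. The stress response list had 2 up with a median of 0.72 (camera adjusted p = 0.000484, and 0.476 with an estimated correlation), and hexosamines 1 up, or 3 adjusted over the list alone (camera adjusted p = 0.0283, 0.558 with an estimated correlation and 0.0585 with the block). No list was called at 3 or 6 h.

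Averaged over the 4 times, 42 genes were called for the drug, 26 up and 16 down, and 125 with the donor block. By the share of all splits of the samples chance could not be excluded for the count of 42 (5 of 100 gave as many, the real one included, highest other 177), but the others follow the donors or keep part of the drug grouping. None of the 19 other splits that part all pairs of the same donor gave as many (highest 30). Total UMIs gave 33 up and 9 down, and the panel's reference genes 13 up and 34 down (median -0.13). SLC7A11 rose on average by 1.66 ± 0.28 (adjusted p = 0.00327), CHAC1 by 1.57 ± 0.25 (adjusted p = 0.00235), SLC17A5 by 0.68 ± 0.08 and GFPT1 by 0.57 ± 0.09. RBKS fell by 0.96 ± 0.11 (adjusted p = 0.000604), PGK1 fell by 0.78 ± 0.15 and SLC16A3 fell by 0.64 ± 0.09. Glycolysis had 7 members down (14 adjusted over the list alone) and none up, and 16 down with the block. Camera gave adjusted p = 8.95e-09, adjusted p = 0.209 with an estimated correlation and 0.0128 with an estimated correlation in the blocked fit. The stress response list had 3 up (6 adjusted over the list alone; camera adjusted p = 0.000475, and 0.474 with an estimated correlation). The average rested mainly on 24 h: without those libraries 6 genes were called (24 with the donor block), and without the 9 h libraries 22 (90 with the block), where RBKS, PGK1, SLC16A3, SLC7A11 and CHAC1 lost their calls without 24 h (adjusted p = 0.37, 0.44, 0.268, 0.159 and 0.0891). Of single libraries, leaving out control 6 h replicate 2 gave 19, control 9 h replicates 1 and 2 gave 21 each, control 24 h replicate 1 gave 20, drug 9 h replicate 1 gave 27 and drug 24 h replicate 1 gave 23.

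**Figure D4:**
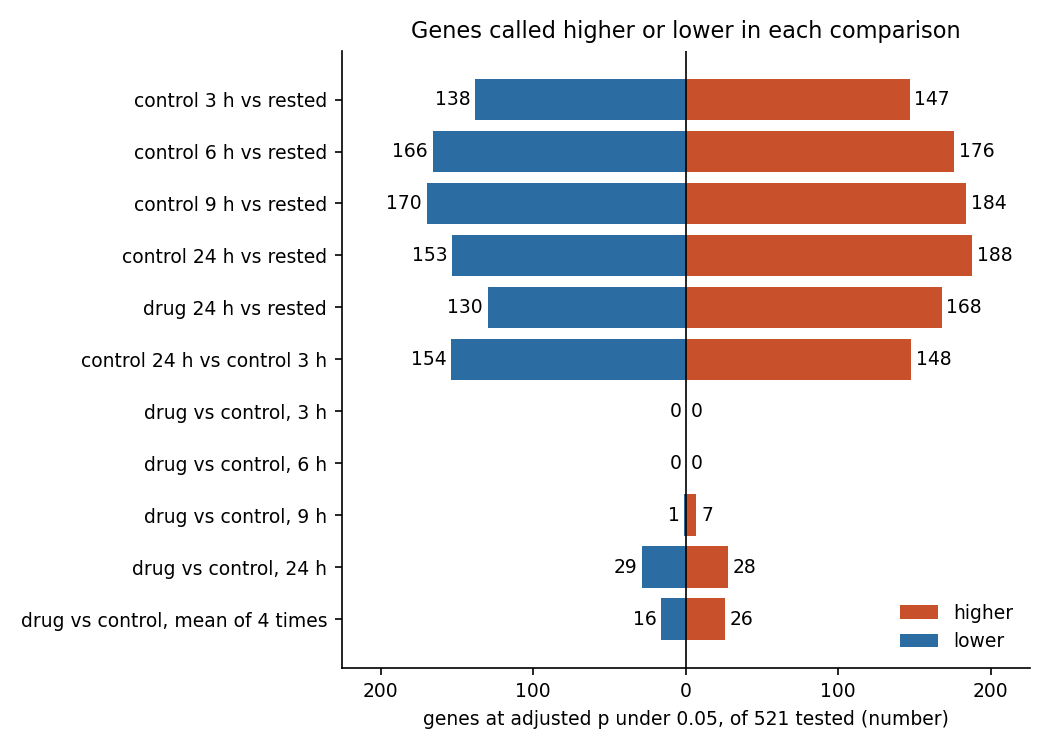
Number of genes called higher (above 0) and lower (below 0) for activation over rested cells and for drug over water at each time, by edgeR's quasi-likelihood test, n = 2 donors per group. Activation called 285, 342, 354 and 341 genes at 3, 6, 9 and 24 h and the drug 0, 0, 8 and 57; scaling by the panel's own reference genes changed the 24 h splits to 286 up and 68 down for activation and 13 up and 73 down for the drug.

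Cells activated with drug for 24 h were also set against rested cells, to ask which activation changes still occur. Here 298 genes differed, 168 up and 130 down (208 and 84 under the panel's reference-gene scaling, median 0.41, and 135 and 152 under reference-gene scaling, median -0.06). ASS1 had 842 UMIs against 1, a ratio of 541 (95% counting interval 96.8 to 21384.2). PHGDH rose by 4.87 ± 0.47 (adjusted p = 9.81e-06), CHAC1 by 6.03 ± 0.66, SLC7A11 by 5.78 ± 0.72 and PSAT1 by 4.21 ± 0.46. All 9 stress response genes rose, with a median of 4.17 (camera adjusted p = 0.000217, and 0.271 with an estimated correlation). Of these, CTH, MTHFD2, PHGDH and PSAT1 are also in the serine and one-carbon list. Serine and one-carbon genes had 10 up and 2 down (11 and 3 adjusted over the list alone; camera adjusted p = 0.0326, 0.271 with an estimated correlation and 0.06 with the block). AMPK and mTOR genes had 7 down and none up (camera adjusted p = 0.0326, 0.492 with an estimated correlation and 0.0574 with the block), or 1 up and 3 down under the panel's reference-gene scaling. Glycolysis had 9 up and 4 down (11 and 4 adjusted over the list alone), with ENO1 still up by 1.98 ± 0.24, PKM by 1.95 ± 0.16, HK2 by 1.45 ± 0.41 and LDHA by 1.11 ± 0.27. PFKFB3, which makes a glycolysis activator, was below its rested level (-2.05 ± 0.25, adjusted p = 4.55e-05), as were GAPDH (-1.02 ± 0.20, adjusted p = 0.00118) and PGK1 (-0.83 ± 0.31, adjusted p = 0.0409). IL10 and IL4 rose by 6.85 ± 1.27 and 5.82 ± 0.61. PDK1 was lower only with the donor block (-0.63 ± 0.30, adjusted p = 0.0879, blocked 0.00016).

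The last comparison asked whether the drug opposes the changes of activation gene by gene. Across 521 genes, which are not independent replicates, the activation change of 1 donor at 24 h was set against the drug change of the other donor, so that no library entered both. Pearson's r was -0.282 and -0.422 for the 2 exchanges, Spearman's rho -0.360 and -0.477, and the covariance -0.332 and -0.572. At 9 h r was -0.246 and -0.203, at 6 h -0.176 and -0.162, and at 3 h 0.087 and -0.119, the sign at 3 h depending on the exchange. Within a donor, where both changes share the control library, r at 24 h was -0.408 and -0.380, beside -0.499 (-0.630 to -0.342) in 100 simulations with no effect. These simulations had no activation change either, so their r follows from the shared library alone. It is no measure for the real r, where activation changes are large. The covariance within a donor was -0.501 and -0.494, beside -0.0607 in the simulations. Of genes called at 24 h 25 rose with activation and fell with drug, against 10.5 for independent lists, and 15 fell and then rose, against 8.22 (66 against 34.3 and 49 against 29.9 with the donor block). In the same direction 7 rose in both, against 10.1, and 1 fell in both, against 8.52 (19 against 36.0 and 4 against 28.5 with the block). Part of this excess may come from the shared controls.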

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

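All tests of explanations in this part were chosen after the result was seen, except those of library depth; the tests of differences between times were set beforehand.

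The drug's effect differed between times for 7 genes, by a test of the effect at 24 h minus that at 3 h (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p, n = 2 per group, same direction in both donors). The difference was 6.08 ± 1.21 for ASS1 (adjusted p = 0.0309), 1.42 ± 0.31 for FYN (0.0477), 1.25 ± 0.27 for SARS, a serine tRNA synthetase (0.0477), and 1.40 ± 0.23 for SLC17A5 (0.00799), all more positive at 24 h. It was -3.51 ± 0.58 for CKB (0.00799), -2.79 ± 0.31 for RBKS (0.000569) and -1.72 ± 0.24 for SLC16A3 (0.00333), all more negative at 24 h. The F test that all 4 drug effects are equal was passed by 5 genes, with F = 19.2 for ASS1 (adjusted p = 0.0127), 15.2 for CKB (0.0289), 35.2 for RBKS (0.00172), 19.5 for SLC16A3 (0.0127) and 12.9 for SLC17A5 (0.0484). ASS1 held 2.97 CPM in control cells at 3 h, so its difference rests on few counts there, and it lost its call with read counts (adjusted p = 0.0711), with only the groups compared (0.0831), and without control 3 h replicate 2 (0.337), control 24 h replicate 2 (0.0556), either drug 3 h library (0.0752 and 0.0552), either drug 9 h library (0.0581 and 0.0559) or drug 24 h replicate 1 (0.0805). The count of 7 became 11 without control 3 h replicate 1, 2 without control 3 h replicate 2, 3 without drug 3 h replicate 1, 4 without either drug 9 h library and 2 without drug 24 h replicate 1. Scaling by total UMIs gave 7 higher and 3 lower in place of 4 and 3, and by the panel's reference genes 1 and 6 (median -0.36). The count of 5 became 3 without either control 3 h library, 3 and 2 without control 24 h replicates 1 and 2, 3 without drug 3 h replicate 1, drug 6 h replicate 2 or either drug 9 h library, and 1 and 2 without drug 24 h replicates 1 and 2. With the donor block 69 genes passed the first test and 44 the second. The effect at 24 h minus 3 h was also lower for the glycolysis list, where no member was called (14 down adjusted over the list alone, 12 with the block), camera gave adjusted p = 8.56e-09, and 0.28 with an estimated correlation (0.0111 in the blocked fit).

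The first pattern weighed is the rise of integrated stress response genes with drug at 24 h (CHAC1, SLC7A11, ASNS, PSAT1 and PHGDH). With all libraries thinned to 720707 UMIs, 5 of 5 were still called higher, which argues against library depth. Under 4 other scalings at least 4 of 5 were still called (PHGDH was lost with the panel's reference genes), which argues against a few abundant genes or the scaling. Without a near-identical copy in another gene are 4 of 5, so reads shared with copies could explain ASNS alone. In control cells at 3 h CHAC1 held 474 and 831 CPM by donor, beside 645 and 581 with drug at 24 h. SLC7A11 held 127 and 320 CPM there, beside 279 and 171, and PSAT1 1481 and 3513, beside 3652 and 4350. Cells at the level of an earlier time of activation were not tested as a cause. A response of the cells to the drug, amino acid or mitochondrial stress for example, is a hypothesis that was not tested. These data do not separate it from other effects of treatment.

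The second pattern is the fall of glycolysis genes at 24 h. After thinning 15 of 15 were still called lower, under each other scaling 15 were, and 13 of 15 have no near-identical copy, which argues against depth, scaling and shared reads. If a share of cells had stayed unactivated at the rested 0 h level, every gene raised by activation would lose the same fraction of its rise. Glycolysis genes lost a median of 0.705 of theirs (13 genes, interquartile range 0.571 to 0.747) and 108 other raised genes 0.291 (-0.017 to 0.538), a difference of 0.414. Of the 15 fallen members 3 (GAPDH, PFKFB3 and PGK1) lay below the rested level with drug. Of these only PGK1 had been called higher with activation in water. These values argue against cells left at the rested 0 h level as the whole cause. The test used the rested level only, so it does not cover cells at the level of an earlier time of activation. Unactivated cells kept for 24 h, with or without drug, were not sampled, and the test does not cover them either. A response of the cells to the drug may be part of the cause, as a hypothesis that was not tested.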

How the results depend on the processing

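The panel's reference-gene scaling and the averages without a time were chosen after the data were examined, and all other alternatives before. The cause was not tested for any change unless stated.

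Of the comparisons of named genes with an alternative, leaving out each library included but activation at 6 and 9 h, drug at 6 h and treated cells left out, 8455 kept direction and side of the threshold, 474 lost their call, 31 gained one and 5 reversed; for gene lists, compared for activation at 3 and 24 h, drug at 3 and 24 h and the drug average only, the numbers were 732, 21, 12 and 0. The counts of genes for activation at each time and at any time, for control 24 h against 3 h and for treated cells stayed within 1.5 times under each alternative, as did that for the drug at 3 h, which stayed at 0.

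Drug at 6 h had 0 genes, and 5 with the DESeq2 test and 2 with the replicate block. Drug at 9 h had 8 genes, and 5 with reference-gene scaling, 1 with the panel's reference-gene scaling, 14 with the DESeq2 test, 3 with limma-voom, 1 without a filter, 27 with the replicate block, 3 with read counts and 0 with only the groups compared. Drug at 24 h had 57, and 86 with the panel's reference-gene scaling and 172 with the replicate block. The drug average had 42, and 125 with the replicate block, 22 without the 9 h libraries and 6 without the 24 h libraries. The drug effect at 24 h minus 3 h had 7, and 31 with the DESeq2 test, 4 with a mean of 50 UMIs, 69 with the replicate block, 4 with read counts and 2 with only the groups compared. The drug by time test had 5, and 18, 3, 44 and 2 with the first 4 of these. The replicate block removes the difference between donors, which lowered the coefficient of variation from 0.257 to 0.128; beyond the calls printed beside their results, it added calls for HK2 (adjusted p = 0.00938), ASNS (0.0218), PDK1 (4.79e-05) and the fatty acid synthesis list (0.0236) in the drug average, for HK2 (0.0139) and PDK1 (0.00026) in control 24 h against 3 h, for PDK1 at activation 3 h (0.0185), and for LDHA (0.00216), ASNS (0.0081) and PDK1 (0.00132) in the drug effect at 24 h minus 3 h. It also added calls for PDK1 at any time of activation (0.00284) and at drug 9 h (0.00346), for PRKAA1 (0.0208) and ASNS (0.0355) at activation 9 h, and for LDHA (0.00886), ASNS (0.0152) and PDK1 (0.00663) in the drug by time test. Among lists it added purine synthesis (0.0463) and T cell activation (0.0463) at activation 6 h, purine synthesis at activation 9 h (0.0293), fatty acid synthesis at drug 9 h (0.0263), and fatty acid synthesis and common reference genes (0.0428 each) in the drug effect at 24 h minus 3 h. In the drug by time test it also added calls for other genes named here. Among them were PGK1 (0.00344), HMGCS1 (0.00162), CD38 (0.00809), FYN (0.0233) and SARS (0.0218), whose results without the block in that test are not printed. It changed no other call that is printed here, while counts of list members also shifted.

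Leaving out 1 library gave 210 to 289 genes for activation at 3 h, 284 to 347 at 6 h, 274 to 355 at 9 h, 279 to 341 at 24 h and 408 to 447 at any time. It gave 224 to 309 for control 24 h against 3 h and 203 to 296 for treated cells. For the drug it gave 0 to 0 at 3 h and at 6 h, 0 to 7 at 9 h, 33 to 64 at 24 h, 19 to 39 for the average, 1 to 5 by time and 2 to 11 for 24 h minus 3 h.

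Reversed were PGM2 at activation 3 h (0.33, and -0.0143 with total UMIs and -0.12 with reference-gene scaling) and ATP5B at activation 3 h (0.40, and -0.0571 with reference-gene scaling). NNT at activation 24 h went from -0.61 to 0.0864 and PRKAA1 from -0.51 to 0.18 with the panel's reference-gene scaling. None of these passed the threshold after the change, and each moved about as far as the median of all genes, from -0.09 to -0.43 and -0.54 at 3 h and from 0.10 to 0.80 at 24 h, so the scaling itself accounts for the change. The correlation of activation and drug effects at 3 h went from 0.087 to -0.119 with the donors exchanged. At 6 h it was -0.176, and -0.152 and -0.190 with prior counts of 0.5 and 5, -0.204 with a mean of 50 UMIs and -0.162 with the donors exchanged. At 9 h it was -0.246, and -0.280 with a mean of 50 UMIs and -0.203 exchanged, and at 24 h -0.282 and -0.422 exchanged.

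Among list tests by camera in those 5 comparisons, 13 of the 21 lost calls came from the estimated correlation and 6 from the panel's reference-gene scaling: at 3 h fatty acid oxidation (adjusted p = 0.0544), the stress response (0.0549) and T cell activation (0.0549), at 24 h cholesterol (0.169) and the stress response (0.198), and cholesterol with drug at 24 h (0.0644). Depth was not the limit for the drug at 24 h, where thinning every library to 720707 UMIs left 60 genes called. Simulated changes of 1.5-fold were recovered there in 30.8%, and in 63.2% with the replicate block.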

Other observations

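All tests of explanations in this part were chosen after the result was seen, except the test of other splits of the samples.

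Of 7 transfer RNA synthetases looked at, 2 were called with drug at 24 h. SARS rose with drug at 24 h by 1.27 ± 0.20 (adjusted p = 0.00232) and MARS, the methionine tRNA synthetase, by 1.22 ± 0.24 (adjusted p = 0.00566), both higher in both donors. EPRS (0.60 ± 0.25) was called only with the donor block (adjusted p = 0.0213, against 0.143), and FARSB, HARS, QARS and EARS2 were not called. PDE3B, a phosphodiesterase, rose by 1.22 ± 0.22. ABAT, which degrades GABA, rose by 0.90 ± 0.18 (adjusted p = 0.00613). ANGPTL4, a secreted lipase inhibitor, fell by 3.53 ± 0.80 and the retinol dehydrogenase DHRS9 fell by 3.18 ± 0.78, but both held under 50 UMIs per library in the higher group. All of these genes were chosen after their values were seen.

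Markers of myeloid cells behaved differently from each other in water. LYZ, the lysozyme gene, went from 46.7 CPM in rested cells to 26.9 at 3 h, 7.5 at 6 h, 2.1 at 9 h and 0 at 24 h, and ALOX5 from 32.5 in rested cells to 6.58 at 24 h. ACSL1 went from 233 to 1167 at 3 h and 254 at 24 h, and TYMP from 237 to 1032 at 6 h and 274 at 24 h. These 2 list members thus rose for a time while LYZ fell, and which cells expressed them was not tested. FBP1 and HK3 were below the filter and not tested. The panel's 10 reference genes had a median of 638 CPM in rested cells, 390 in control cells at 24 h and 606 in drug cells at 24 h.

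The drug's changes ran against those of activation across the panel at 24 h, and this was tested outside glycolysis and the integrated stress response. Without both lists, 492 genes gave a Pearson r across donors of -0.316 and -0.491, so the opposition may extend beyond those lists. Genes are not independent replicates, and the 2 donors' cells are the only replicates. If glycolysis genes fell only as far as the drug opposes activation in general, they would lie on the line of the other genes. That line was fitted to all genes outside glycolysis, with the 9 stress response genes kept. Those 9 lay above it (median residual 1.44 and 1.91), and a line without them was not fitted. The median residual of glycolysis genes was -0.606 in 1 exchange and -0.738 in the other, below that line in both. This argues against the general opposition as the whole cause.

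The count of 42 genes for the drug average was set against other splits of the 16 activated libraries within each time. Of 100 splits drawn, 5 gave as many genes, the real one included, so by this share chance cannot be excluded for the count without the block. Of the 4 others 3 follow the donors at 2 or more times, the highest with 177, which points to a structure of the samples, and 1 keeps the drug grouping at 9 and 24 h (57 genes), so they are no measure of a paired comparison without change. Among the 19 other splits drawn that part all pairs of libraries from the same donor, as the real one does, the highest count was 30, in a split that keeps the drug grouping at 6, 9 and 24 h. With the donor block the real split gave 125, and the highest others, 134 and 112 among those that part all pairs, are these same 2 splits that keep part of the drug grouping.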
